A study of Homo sapiens with 8 samples.

How the data were processed

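The data are small RNA sequencing counts from microvesicles of MCF7 and HCT116 cells treated with Akti-1/2 or DMSO. Per the labels' protocols, vesicle RNA was isolated with a commercial exosome RNA kit, libraries were made with a small RNA kit that ligates an adapter to each end, and a gel slice holding small inserts was cut out. The authors deposited raw read counts per annotated feature in a single table with 8 columns, which is the unit used here. The submitters' processing notes name cutadapt 1.2.1, Bowtie 1.0, HTSeq and the hg19 and GRCh37.p13 builds. How reads with several matches and strand were handled is not given in the sources used here, so near-identical copies and overlapping features are uncertain. A microRNA hairpin row does not tell the arms apart.

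The table has 35310 features and 5 tally rows. The tally rows name no gene and stayed out of library sizes and tests, and reads without a feature made up 14.9% to 19.6% of the reads of a column. Column names were matched to samples by line and AKT state, and 0 columns belonged to no sample. Symbols and RNA classes came from GENCODE release 29 by exact gene identifier without its version. It is built on GRCh38, so no coordinates are given. It matched 30839 features and left 4471 unmatched, of which 237 had counts. These hold 50.3% of the counted reads and are given by identifier or left unnamed. MIR21, MIR34A, MIR1246 and RNY4 were not analysed here under those symbols. Some host gene rows have exons that contain a microRNA with no row of its own, such as MIR22HG with MIR22.

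The paired columns of each group were compared by chi-square over features with at least 10 counts in the pair. Chi-square per degree of freedom was 2.91, 3.62, 1.58 and 1.61 for MCF7 DMSO, MCF7 Akti, HCT116 DMSO and HCT116 Akti, and 1.05, 1.15, 1.17 and 1.27 without the features that differed, of which there were 6, 8, 3 and 2. The column totals stood in a ratio of 1.04 in each group. The columns therefore differed by little more than sampling noise and were counted as 1 sample per group.

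Before the data were examined, the main test was set as edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the counts of all 8 columns, with TMM scaling, edgeR's expression filter, 4 group means and Benjamini-Hochberg adjustment at 0.05. It was kept, but with 1 library per group its p-values describe these libraries. The contrasts were Akti-1/2 against DMSO in each line, the difference of those responses, and MCF7 against HCT116 in DMSO. Overlap was tested with Fisher's exact test; the comparisons of the 2 lines share no library. Class shares have 95% Wilson intervals from the summed columns. Of 33 gene lists fixed beforehand, the 14 with at least 3 tested members were tested with camera (limma 3.58.1, preset correlation 0.01). After the data were seen, the percentile of each list's median among 10000 random lists matched on expression and a fit of the summed columns over both lines, on features with at least 20 counts in each line, were added. Folds against a library at 0 counts are bounds against 3 counts over the group, and ratios with 1 to 3 counts have exact binomial intervals, both per counted read and for counting error only.

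Features named follow a rule set beforehand. Per contrast it takes the 6 largest differences in each direction with adjusted p under 0.05, at least 20 CPM (counts scaled to the column total) in the higher group and columns that do not overlap. It adds the 2 members with the lowest p of each list with a called member, the 5 most abundant features, MIR210 and the other microRNAs and Y RNA named above, and for the difference of responses the 5 lowest p-values in each direction. Outside the rule, MIR200A and MIR107 in both lines, MIR26B and MIR182 in MCF7, MIR106B, MIR342, MIR132, MIRLET7D, MIRLET7E, RNU2-2P and SNORD42A in HCT116, and the copies that differ between columns, were named after their values were seen.

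Alternatives covered RLE, upper-quartile and no scaling factors, other filters, DESeq2 1.42.0, voom, a replicate block, each column left out, microRNAs alone, and the 10 most abundant features left out. Hairpin GC was taken from release 29 transcripts and was found for 216 of 216 tested microRNAs. The count test was checked on simulated counts with 200 changed features. For the checks of single lines each feature was simulated at its mean share over all groups, with a fixed dispersion. These are not the levels or the spread of that line. For MCF7, on 379 features, it recovered 80% of 2-fold and 98% of 4-fold increases and 74% and 88% of decreases of these sizes, with 4 false calls. For HCT116, on 352 features, it recovered 74% and 92% of increases but 38% and 72% of decreases, with 4 false calls. In the data 88 of 400 tested features had 3 counts or fewer in both HCT116 libraries, so these rates need not hold there. The fit over both lines recovered 40% of 4-fold and 96% of 16-fold increases, and 40% and 90% of such decreases, on 400 features, with 10 false calls among 143. Python 3 with numpy, pandas and scipy made the tables.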

Results

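Small RNA was sequenced from microvesicles, the membrane-bound particles that cells shed into their medium, of 2 human cancer cell lines. MCF7 is an established breast adenocarcinoma line and HCT116 an established colon carcinoma line. Cells were treated for 72 h with Akti-1/2, an allosteric inhibitor of the kinases AKT1 and AKT2, or with its vehicle DMSO. The inhibitor was used at 2 µM in MCF7 and at 20 µM in HCT116, so that line and dose change together. The 4 groups have 2 count columns each, which the submitters describe as technical replicates. Counted reads per column were 2604054 and 2508676 for MCF7 DMSO, 1864466 and 1793791 for MCF7 Akti-1/2, 1546158 and 1489450 for HCT116 DMSO, and 787146 and 756149 for HCT116 Akti-1/2.

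Apart from 9 features, the paired columns differed by about the sampling noise of reads, with chi-square per degree of freedom between 1.05 and 1.27 in the 4 groups. Each pair was therefore counted as 1 sample, here called the DMSO or Akti library of its line, and n = 1 per group. The adjusted p-values below come from edgeR's quasi-likelihood test with the columns entered separately. They compare the reads of single libraries, not the conditions, and none of the differences has a replicate check of separate cultures. Standard errors and intervals likewise cover no variation between cultures. The standard errors come from edgeR's quasi-likelihood F statistic. Some are below the error of counting alone, as for SNORD33 and MIR93 in HCT116, so they and the adjusted p-values can overstate precision. The depth differs by 3.31 times between the deepest and the shallowest library, and the HCT116 Akti library gives the least precise values.

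The first question was which classes of RNA the vesicle libraries held. MicroRNAs named in the annotation used, GENCODE release 29, took 44.2% of counted reads in the MCF7 DMSO library and 38.6% in the MCF7 Akti library. Features not in that release took 42.2% and 49.98% there. Long non-coding RNA, mostly the row of MIR22HG, whose exon holds MIR22, took 11.9% and 6.98%. Spliceosomal and other small nuclear RNAs (snRNAs) rose in share from 0.368% to 0.705% and small nucleolar RNAs (snoRNAs), which guide chemical modification of other RNAs, from 0.318% to 0.554%. Y RNAs, small RNAs bound by the Ro60 protein, went from 0.696% to 1.13%. The class of RNase MRP and P RNA, here RMRP, the RNA component of an endonuclease that acts on precursor ribosomal RNA, went from 0.214% (95% Wilson interval 0.210 to 0.218) to 1.94% (1.93 to 1.96). Vault RNAs, the RNA part of vault particles, took 0.00196% and 0.0198%. In HCT116 the microRNA share was 37.1% in the DMSO library and 40.9% in the Akti library, that of features not in the release 61.7% and 55.0%, and that of long non-coding RNA 0.796% and 3.20%. There the snRNA share was 3.10 times and the Y RNA share 2.79 times as high in the Akti library, while the snoRNA share was 0.894 times as high. RMRP had 49 counts in the HCT116 DMSO library and 77 in the HCT116 Akti library. A single feature, whose identifier has no name in the annotation used, took between 36.5% and 47.0% of the reads of every column. The class of such unmatched features was not determined, so the named microRNA share need not be that of all microRNAs. In MCF7 the Akti to DMSO ratio of the named microRNA share was 0.874, and 0.954 without that feature.

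**Figure D1:**
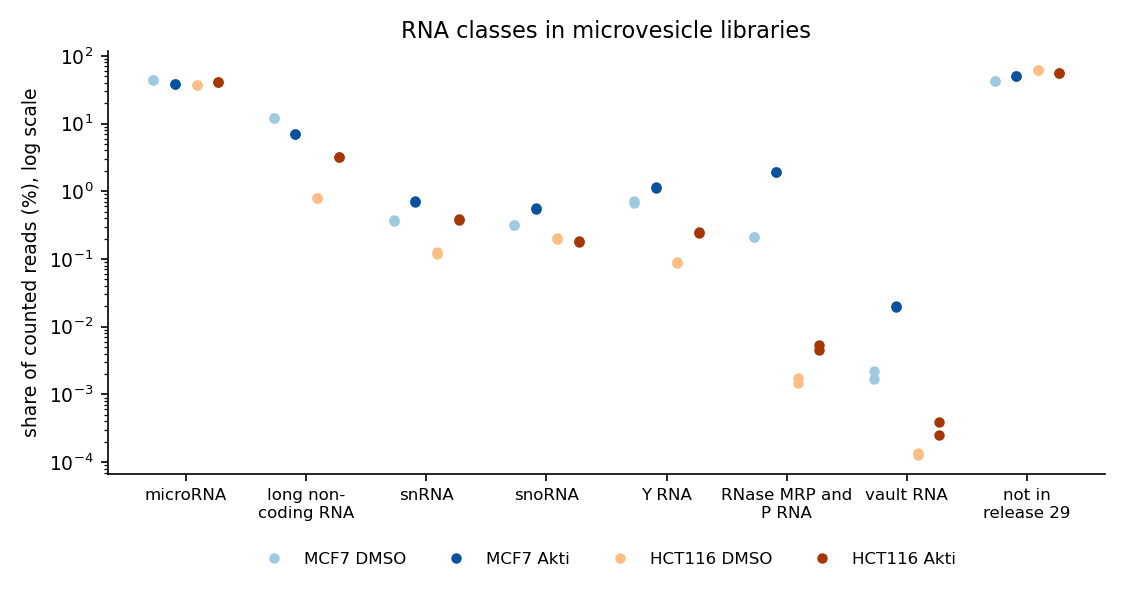
Share of counted reads per RNA class (percent, log scale) in the 8 count columns, 1 point per column, with the 2 columns of a group in 1 colour. The points of RNase MRP and P RNA lie near 0.214% in MCF7 DMSO and 1.94% in MCF7 Akti, and those of snRNA at 0.368% and 0.705%.

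In MCF7, structural small RNAs and a set of microRNAs were higher in the Akti library, and several abundant microRNAs were lower. RMRP was higher by 3.15 ± 0.05 on the log2 scale (SE; 10926 counts in the DMSO library and 71077 in the Akti library), and the vault RNAs VTRNA1-1 and VTRNA1-2 by 3.53 ± 0.25 and 2.51 ± 0.37. MIR210, the microRNA best known for its induction in hypoxia, had 197 counts in the DMSO library and 2700 in the Akti library, a log2 fold change of 4.22 ± 0.17 (edgeR adjusted p = 1.73e-17). It was the only 1 of 5 tested hypoxia and stress microRNAs called higher in MCF7. Of the list 1 was lower and 3 were not called (median -0.28). MIR339 (5.04 ± 0.22) and MIR1180 (3.87 ± 0.24) were higher too. SNORD3A, the U3 RNA of early ribosomal RNA cleavage, had 3 counts against 114, a ratio of counts per counted read of 53.1 (exact 95% interval 17.7 to 261). SNORD67 was higher by 4.75 ± 0.29.

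Of the 400 features tested, 196 passed an adjusted p of 0.05 in MCF7, 125 of them higher and 71 lower in the Akti library. At least 2-fold differences were mostly upward, with 86 features higher and 9 lower. With upper-quartile scaling the split was 101 higher and 108 lower, and that scaling moved the median log2 fold change by -0.18. Without the first MCF7 Akti column the named fold changes moved by a median of -0.27. Among features with at least 20 CPM in the higher group and columns that do not overlap, the largest lower differences were those of RNA5SP218, a 5S ribosomal RNA pseudogene (-1.52 ± 0.23), MIR412 (-1.42 ± 0.24), MIR541 (-1.28 ± 0.23), MIR130A (-1.03 ± 0.06), MIR33A (-1.01 ± 0.22) and MIR381 (-0.996 ± 0.159). Among the most abundant features, the row of MIR22HG was lower (-0.91 ± 0.03).

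By group, 26 of 53 C/D box snoRNAs tested in MCF7 were higher and 2 lower, the same counts when adjusted over the list alone. SNORD67 and SNORD42A (2.37 ± 0.12) were the members with the lowest p. Their median log2 fold change of 0.78 stood at percentile 99.9 among 10000 random lists matched on expression, and at 0.82 with the 3 members at 3 counts or fewer in both libraries left out. H/ACA box snoRNAs had 9 of 19 higher and 0 lower (percentile 90.3; 9 adjusted over the list alone), among them SNORA33 (1.72 ± 0.30) and SNORA26 (1.30 ± 0.23). Of 30 spliceosomal snRNAs, 17 were higher and 0 lower (median 0.75, percentile 99.5; 17 adjusted over the list alone), with RNU5E-1 at 0.89 ± 0.05 and RNU5B-1 at 1.26 ± 0.10. Many snRNA rows are near-identical copies or pseudogenes that can share reads, so single copies are uncertain. Of 4 scaRNAs, which guide modification of snRNAs, 2 were higher, SCARNA11 (1.36 ± 0.24) and SCARNA22 (0.65 ± 0.25), the second not past the threshold when 1 column was left out in 4 of 8 cases. Medians of these lists were above 0 under each of the 4 scalings.

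Of 5 listed members of the miR-200 family, which maintains epithelial identity, 3 were tested. All 3 were lower in MCF7: MIR429 (-0.42 ± 0.05), MIR200B (-0.56 ± 0.08) and MIR200A (-0.25 ± 0.05). Whether members of a family are transcribed together was not tested, so they may not be independent. Of 9 microRNAs linked to AKT and FOXO signalling, 5 were lower, with MIR27A at -0.74 ± 0.03 and MIR27B at -0.34 ± 0.03, and 1, MIR26B, was higher at 0.13 ± 0.04, less than upper-quartile scaling moved the median. Among 7 microRNAs often found in extracellular vesicles 5 were lower, including MIR30D (-0.66 ± 0.04) and MIR151A (-0.60 ± 0.04), and MIR320A was higher (1.18 ± 0.09). Adjusted over the list alone the lower counts were 3, 5 and 6. Within the miR-17-92 family MIR25 was lower (-0.57 ± 0.03). In the let-7 family 2 of 7 were higher and 2 lower (3 and 2 adjusted over the list alone), and its median of 0.11 was -0.08 with upper-quartile scaling. Among 7 luminal breast microRNAs MIR375 was higher (1.39 ± 0.10) and MIR149 lower (-0.65 ± 0.14). Of 216 microRNAs in all, 38 were higher and 58 lower, but 58 higher and 44 lower when microRNAs were fitted alone. A preset-correlation set test (camera) called the C/D box, snRNA, vesicle, AKT and FOXO, and miR-200 lists. With an estimated correlation the adjusted p-values of these 5 lists were 0.263, 0.263, 0.389, 0.484 and 0.389.

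In HCT116, a set of microRNAs was higher in the Akti library and another set was lower. MIR320A (3.52 ± 0.10; 133 counts against 1240), MIR93 (3.23 ± 0.07; 113 against 865), MIR149 (3.07 ± 0.31) and MIR33B (2.94 ± 0.17) were higher in the Akti library. So were MIR25 (2.47 ± 0.03; edgeR adjusted p = 1.84e-28), MIR191 (2.00 ± 0.03), MIR100 (1.78 ± 0.05) and the MIR22HG row (1.69 ± 0.03). The snoRNAs SNORD33 (3.89 ± 0.18; 8 counts against 98) and SNORD100 (3.08 ± 0.43) were higher as well. MIR190A (-3.09 ± 0.50), MIR450B (-2.60 ± 0.19), SNORD57 (-2.44 ± 0.42), MIR1252 (-2.08 ± 0.30), MIR1255A (-2.05 ± 0.26) and SNORD45C (-2.05 ± 0.34) were lower. MIR210 had 1 count in the DMSO library and 7 in the Akti library. Its ratio of counts per counted read, without scaling factors, was 13.8 (exact 95% interval 1.77 to 621).

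In total 197 of 400 features passed in HCT116, 99 higher and 98 lower, with 72 and 67 at least 2-fold. Without scaling factors the split was 130 and 44, and the median log2 fold change moved by 0.52. That median includes features with hardly any HCT116 counts. The 42 microRNAs at least 2-fold higher moved by a median of 0.67. HCT116 fold changes also moved with the count columns used, by a median of -0.49 without the first HCT116 DMSO column. Differences below about 0.67 therefore depend on the scaling. In 14 of the 197 calls an HCT116 library had 3 counts or fewer.

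Of 15 listed members of the miR-17-92 family and its paralogs, a group of growth-promoting microRNAs, only 3 were tested, and MIR17 was not among them. All 3 were higher in the HCT116 Akti library (median 2.47, percentile 98.5), but they may not be independent of each other. These were MIR25, MIR93 and MIR106B (0.77 ± 0.09). The miR-200 family was lower in all 3 tested members, with MIR429 at -1.17 ± 0.05, MIR200B at -0.93 ± 0.08 and MIR200A at -0.29 ± 0.05. The difference of MIR200A is smaller than the shift of 0.67 seen without scaling factors, so its direction depends on the scaling. In the let-7 family, growth-restraining microRNAs, 6 of 7 were lower and 1 higher (median -0.996, percentile 4.96), with MIRLET7G at -1.02 ± 0.05 and MIRLET7F1 at -1.78 ± 0.24. Among the lower ones, MIRLET7D (-0.28) and MIRLET7E (-0.44) also differed by less than that shift. Of the vesicle microRNAs 5 of 7 were higher, with MIR30D at 1.67 ± 0.04, and MIR10B was lower (-0.87 ± 0.04). Of the AKT and FOXO microRNAs 3 were higher, among them MIR23A (1.43 ± 0.05) and MIR27B (0.49 ± 0.03, but -0.01 without the first HCT116 DMSO column), and 4 lower, among them MIR182 (-1.03 ± 0.03) and MIR26B (-1.19 ± 0.04). MIR375 (2.21 ± 0.20) and MIR342 (1.65 ± 0.16) of the luminal breast list were higher from 19 and 25 counts. Counts adjusted over each list alone were the same for these lists.

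Structural RNAs in HCT116 went both ways. Of 30 snRNAs 13 were higher, with RNU5E-1 at 1.84 ± 0.06 and RNU5A-1 at 1.39 ± 0.10, and 1 lower, RNU2-2P (-1.77 ± 0.13). Of 53 C/D box snoRNAs 8 were higher and 15 lower, with SNORD1B at -1.63 ± 0.13 and SNORD42A at -1.42 ± 0.11. Their median of -0.57 stood at percentile 0.16 and was 0 without scaling factors and -0.68 with the 8 members at 3 counts or fewer in both libraries left out. Among 4 scaRNAs 2 were higher, SCARNA3 (1.79 ± 0.29) and SCARNA11 (2.13 ± 0.43). For 19 H/ACA box snoRNAs the counts were 2 higher and 1 lower, and 2 and 0 adjusted over the list alone. The camera test called the miR-17-92 and miR-200 lists, with an adjusted p of 0.424 for each when the correlation was estimated.

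Differences in HCT116 went with the GC content of the microRNA hairpin, while in MCF7 the link was weaker. Among 87 microRNAs with at least 1000 counts over all libraries, the Spearman correlation was 0.60 in HCT116 and -0.03 in MCF7. Across 216 microRNAs, which are not independent replicates, the log2 fold change had a Spearman correlation of 0.59 with the GC content of the hairpin in HCT116 and of 0.15 in MCF7, and a Pearson correlation of 0.56 and 0.36. Of the 216, 42 had 3 counts or fewer in both HCT116 libraries, and 8 in both MCF7 libraries. They entered these correlations and the linear trend below, which rest partly on thin counts. The median hairpin GC was 56.0% for the 42 microRNAs at least 2-fold higher in the HCT116 Akti library and 38.9% for the 41 at least 2-fold lower. In MCF7 it was 61.4% for the 29 at least 2-fold higher and 47.8% for the 7 at least 2-fold lower, against 48.1% for all 216. Weighted by reads, hairpin GC was 44.7% in the first HCT116 DMSO column, 46.2% in the first HCT116 Akti column and 49.2% in the first column of both MCF7 groups. Hairpin GC was 63.1% for MIR25, 60% for MIR93 and 59.8% for MIR191 and MIR320A, which were higher in HCT116. To remove a linear GC trend, the fitted trend was subtracted and the median log2 fold change of the 216 added back. This centring lowered values by itself. MIR107, at a GC of 46.9%, went from 2.08 to 1.87 in HCT116 and from -0.50 to -0.76 in MCF7. Part of each change with the trend removed therefore comes from centring, not from GC. In HCT116, 21 of the 42 microRNAs at least 2-fold higher stayed so, among them MIR320A (2.15), MIR93 (1.84), MIR100 (1.62) and MIR30D (1.56). Others kept less of the difference: MIR25 was at 0.80, MIR191 at 0.63, MIR149 at 0.61, MIR33B at 0.38, MIR23A at 0.27 and MIR375 at 0.17. MIR106B (61.0%) and MIR27A (60.3%) turned to -0.71 and -0.34. Of the 41 at least 2-fold lower in HCT116, 18 stayed so. Among the microRNAs named above as lower, MIR190A was at -2.16, MIR450B at -1.13, MIR1255A at -1.07 and MIR1252 at -0.42. The miR-200 family went against this trend, being lower at 57.8% (MIR429), 60% (MIR200B) and 55.6% (MIR200A), and MIRLET7G was lower at a hairpin GC close to the median of the tested microRNAs. In MCF7, with the linear trend of that line removed, MIR339, MIR210 and MIR1180 were at 3.76, 2.97 and 2.74.

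**Figure D2:**
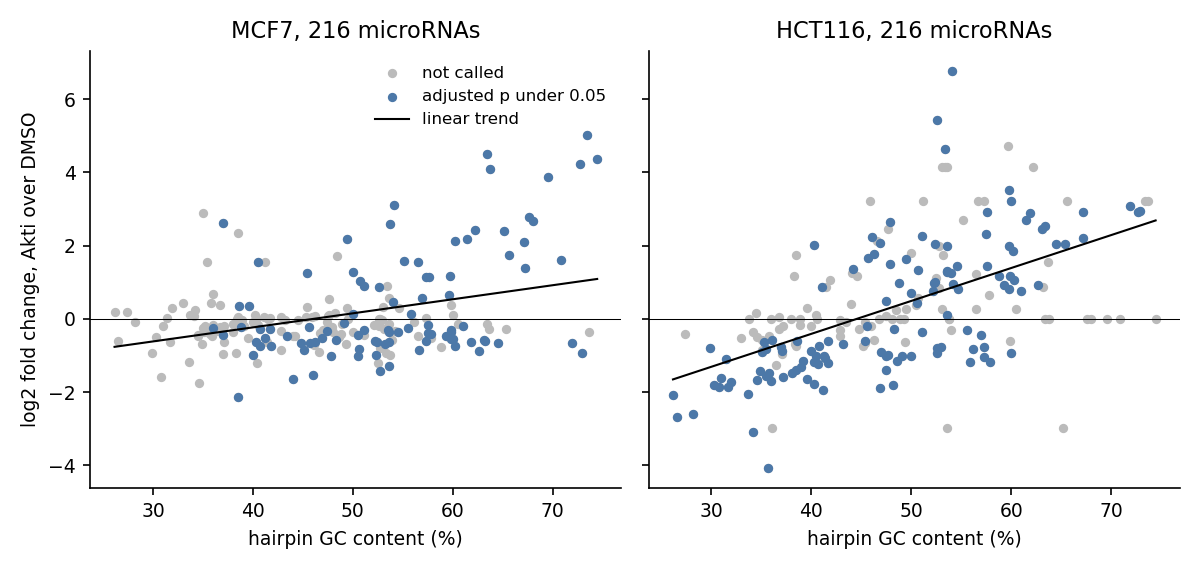
Log2 fold change of 216 microRNAs, Akti over DMSO library, against the GC content of the hairpin (percent) in MCF7 on the left and HCT116 on the right. Each point is a microRNA, blue where the edgeR adjusted p was under 0.05, and the line is a linear trend; the Spearman correlation was 0.15 in MCF7 and 0.59 in HCT116.

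The responses of the lines were then set against each other. The 29 features higher in both lines compared with 30.9 for independent lists (Fisher's exact test, two-sided, p = 0.708), and the 18 lower in both with 17.4 (exact p = 0.879). More features than independent lists would give were lower in MCF7 and higher in HCT116, 36 against 17.6 (Fisher's exact test, p = 2.04e-07). Another 21 were higher in MCF7 and lower in HCT116, against 30.6 (Fisher's exact test, p = 0.0171). Across the 400 features the fold changes of the lines had a Pearson correlation of -0.02 and a Spearman correlation of -0.02. Of these features 88 had 3 counts or fewer in both HCT116 libraries and 12 in both MCF7 libraries. Such features could hardly be called there. The expected numbers, p-values and correlations above do not allow for this, and features are not independent replicates. MIR320A, MIR375, RNU5E-1 and RMRP were higher in both Akti libraries, although RMRP in HCT116 (0.95 ± 0.13) was 0.34 without the first HCT116 DMSO column. With the GC trend removed MIR375 fell to 0.35 in MCF7 and 0.17 in HCT116, and MIR320A to 0.42 and 2.15. When the columns were summed and both lines fitted with line as a term, 0 of 235 features passed by edgeR, voom and DESeq2, and 4 had an unadjusted p under 0.05 by edgeR.

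The test of the difference itself called 153 features, 77 with a more positive and 76 with a more negative difference in MCF7. The split was 62 and 92 with upper-quartile scaling and 46 and 117 without factors. MIR25 differed by -3.04 ± 0.04, MIR22HG by -2.60 ± 0.04, MIR191 by -2.36 ± 0.04, MIR30D by -2.33 ± 0.05 and MIR27A by -1.81 ± 0.05. These 5 rows were lower in the MCF7 Akti library and higher in the HCT116 Akti library, but with the GC trend removed MIR27A was at -0.34 in HCT116. SNORD42A (3.78 ± 0.17) and the long non-coding RNA AL360012.1 (2.90 ± 0.08) went the other way. MIR577 (2.01 ± 0.08) and MIR182 (1.04 ± 0.04) were lower in the HCT116 Akti library, and MIR182 was at 0.01 ± 0.03 in MCF7. Of the C/D box snoRNAs 14 had a positive and 3 a negative difference (percentile 99.9). Camera called this list, miR-17-92 and the vesicle list, with adjusted p-values of 0.451, 0.451 and 0.564 with an estimated correlation.

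**Figure D3:**
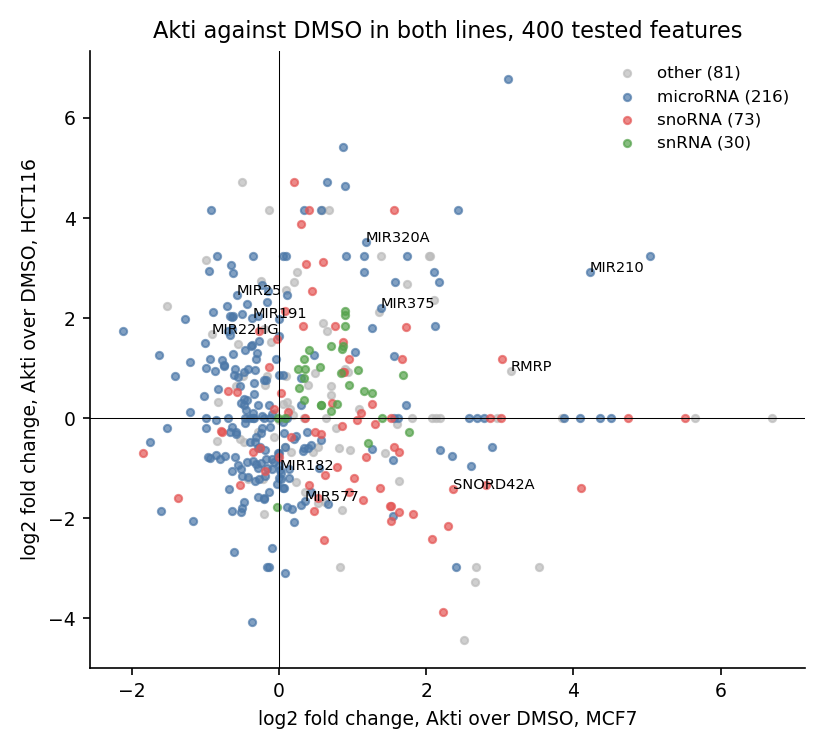
Log2 fold change of Akti over DMSO library in MCF7 (horizontal) and HCT116 (vertical) for the 400 tested features, coloured by RNA class. The cloud has no overall slope (Pearson correlation -0.02), MIR25, MIR191 and MIR22HG lie to the upper left, and points on the horizontal line at 0 include features without counts in HCT116.

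The vehicle libraries of the lines served as the background for these comparisons. Between MCF7 and HCT116 in DMSO 342 of 400 features differed, 202 higher and 140 lower in MCF7, and 157 and 163 with upper-quartile scaling, which moved the median by -0.82. In 113 of these calls a library had 3 counts or fewer. Against a floor of 3 counts over the group, MIR127 was at least 434-fold higher in MCF7, MIR708 at least 67.1-fold, MIR744 at least 54.4-fold, MIR615 at least 40.4-fold and MIR3909 at least 33.4-fold. These folds, and the folds and ratio that follow, are per counted read, without the scaling factors of the log2 values. MIR598 had 1404 counts against 1 in HCT116. MIR135B was at least 98.8-fold and SNORD14D at least 49.4-fold lower in MCF7. MIR651 had 3 counts in MCF7 and 556 in HCT116, a ratio of 312 (exact 95% interval 106 to 1518). MIR342, a luminal breast microRNA, and MIR375 of the same list had 10063 and 3024 counts in the MCF7 library and 25 and 19 in HCT116. Of this list 5 of 7 were higher in MCF7 (median 5.77, percentile 99.5; 5 adjusted over the list alone). The miR-200 family was lower in MCF7 in all 3 tested members (median -2.43, percentile 8.84), a list that camera called (adjusted p = 0.726 with an estimated correlation). The 3 tested miR-17-92 members were higher in MCF7 (median 3.43), and 5 of 7 let-7 members were lower (median -1.97). Across the 216 microRNAs the difference between the DMSO libraries had a Spearman correlation of 0.49 with hairpin GC.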

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

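The tests for MCF7 reads in an HCT116 library and for carried-over cellular RNA, the per-line test of the Y RNA sum, the fit without abundant features for the first pattern, and the decision to keep fits without a column out of its scaling test, were chosen after the results were seen. The difference of the Akti responses between the lines was called for 153 features by edgeR's quasi-likelihood test, which compares single libraries. In log2 units, MCF7 minus HCT116, the named ones were AL360012.1 at 2.90, MIR577 at 2.01, MIR182 at 1.04, SNORD42A at 3.78 and the unnamed ENSG00000252310.1 at 2.22, and on the other side MIR25 at -3.04, MIR22HG at -2.60, MIR191 at -2.36, MIR30D at -2.33 and MIR27A at -1.81. Line and dose (2 µM against 20 µM) change together here.

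The first pattern is the set of microRNAs at least 2-fold higher in an Akti library, 29 in MCF7 and 42 in HCT116. Scaling by a few abundant features is argued against as the whole cause in MCF7. There at least 86.2% of the set stayed 2-fold higher under 3 other scalings and without the 10 most abundant features. Without the first MCF7 Akti column 85.7% did. In HCT116 at least 89.7% stayed so under the same settings, which met the limit set beforehand. Of these settings only RLE and leaving out the 10 most abundant features lowered the HCT116 set, by a median of -0.03 and -0.20. Under that limit, however, were the 71.4% without the first HCT116 DMSO column and the 78.05% without the second HCT116 Akti column. The HCT116 verdict therefore holds only with fits without a column kept out of the test. Reads of the MCF7 libraries in the HCT116 Akti library are also argued against, because 11 microRNAs found in MCF7 and nearly absent from HCT116 DMSO gained a median of 0.308% of their MCF7 level, against 27.4% for the pattern. Removing a linear trend on hairpin GC left 50% of the HCT116 set 2-fold higher (21 of 42; median log2 fold change 2.04 ± 1.16 SD before and 1.02 ± 1.25 after), at the limit set beforehand, and 65.5% of the MCF7 set (19 of 29; 2.17 ± 1.16 and 1.44 ± 1.03). Values were centred on the median of the tested microRNAs in that step, which by itself lowered them. A GC-dependent difference in library preparation and a response to the inhibitor at either dose therefore cannot be told apart for these microRNAs, with 1 library per group; among 87 abundant microRNAs the Spearman correlation with GC was 0.60 in HCT116 and -0.03 in MCF7.

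The second pattern is the higher share of snRNA and Y RNA in both Akti libraries, with the snoRNA share 1.74 times as high in the MCF7 Akti library and 0.894 times as high in the HCT116 Akti library. If RNA of whole or dying cells were carried into the preparation, all classes would rise by a like factor, provided that cells and vesicles hold them in like proportions. The highest ratio of shares was 5.61 times the lowest in MCF7, across snRNA, snoRNA, Y RNA and RNase MRP and P RNA, and 3.47 times in HCT116, across snRNA, snoRNA and Y RNA. That proviso is untested, because no whole-cell library was analysed here, so carried-over RNA and a change in vesicle content cannot be told apart in either line.

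The third pattern is the few features that differ between the paired columns of every group, where the design gives no biological explanation. A Y RNA copy of the Rfam family RF00019 had 37 and 754 counts in MCF7 DMSO and 28 and 894 in MCF7 Akti, and RNU2-3P had 31 and 163 and 19 and 149. Summed over the Y RNA copies named in the annotation, the columns departed from the ratio of their totals by up to 5.15%, but the whole shift of that copy is at most 4.22% of the sum, which the limit of 10% set beforehand could not detect. In MCF7 the sum was short in the first column by at least 2.58 SD of counting noise in both groups (958 reads in DMSO and 640 in Akti by column totals, where that copy was short by 746 and 901), which argues against sharing among the named Y RNA copies as the whole cause there. In HCT116 the shortfall was -0.881 SD in DMSO and 1.29 SD in Akti at the lowest, and the other copies gained at most 1.72 SD, so counts are too few there. Summed over named U2 snRNA copies the departure reached 22.4%, and it was over 10% in each group, which argues against sharing among the named U2 copies as the whole cause. Sharing among the named Y RNA copies in HCT116, and sharing with copies outside the annotation, stay open.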

How the results depend on the processing

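Scaling, columns and features set most limits; where a value moved, the cause was not tested unless fewer features were tested. DESeq2 called 130 features in MCF7. With microRNAs alone, fewer features were tested and the calls were 102 in MCF7, 120 in HCT116, 101 for the difference and 187 between the lines; the list calls were 0 in MCF7, 1 in HCT116 and 0 between the lines. At an adjusted p of 0.01 the features changed alike in both lines were 31 rather than 47. The fit over both lines was chosen after seeing the data. It called 5 features with every feature tested per line and 1 with no filter. The other settings gave 0, 0, 0, 0 and 0. Camera called 5, 2, 3 and 1 lists in the 4 contrasts, 0 in each with an estimated correlation, and fry, which asks another question, 12, 13, 8 and 14. Without the most abundant feature the Akti to DMSO ratio of shares in MCF7 was 0.954 for microRNA, 2.09 for snRNA, 1.90 for snoRNA, 1.77 for Y RNA and 9.92 for RNase MRP and P RNA, and 1.11 for microRNA in HCT116. Without scaling factors ENSG00000199004.1 in HCT116 was at 0.0072 and MIR16-2 between the lines at 0.050, both of the other sign otherwise. Leaving out each column in turn gave 153 to 206 calls in MCF7, 167 to 188 in HCT116, 135 to 148 for the difference, 307 to 355 between the lines and 37 to 49 features alike in both lines. MIR15B in HCT116 ranged from -0.456 to 0.0516, MIR27B in HCT116 from -0.0084 to 0.506 and ENSG00000199004.1 in MCF7 from -0.11 to 0.21. Of the named features' 1239 values with a column left out, 33 lost their call, 8 gained one and 9 changed sign. With the features that differ between columns left out, chosen after seeing the data, calls were 198, 187, 147 and 329. Removing the GC trend with centring on the median, also added, left 19 and 21 microRNAs 2-fold higher. Of those 2-fold lower it left 7 of 7 in MCF7 and 18 of 41 in HCT116.

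Deviations of same-numbered columns correlated at 0.43 between the MCF7 groups, 0.03 between the HCT116 groups and 0.15 to 0.27 across lines, and at -0.09 to 0.06 without the 9 differing features, 2 of which differed the same way by column number in all 4 groups. As 1 pair lay under 0.1, the main test was kept without a replicate block. That correlation cannot exclude something shared by same-numbered columns. The 2 features above and the ratio of column totals, 1.04 in each group, point to it. With a replicate block the calls were 214, 190, 159 and 345, the features alike in both lines 50, and the list calls 5, 3, 3 and 0, the last without the miR-200 list between the lines.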

Other observations

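Single members of other lists were also called. Of 9 mesenchymal and stromal microRNAs, MIR100 was lower in the MCF7 Akti library (-0.65 ± 0.06) and higher in the HCT116 Akti library (1.78 ± 0.05), and MIR381 was lower in MCF7 (-0.996 ± 0.159). Of 5 hypoxia and stress microRNAs, MIR146B was lower in HCT116 (-0.81 ± 0.05) and MIR132 higher (2.04 ± 0.21, and 0.17 with the hairpin GC trend removed). Of 3 miR-15/16 family members MIR16-2 was lower in both lines (-0.44 ± 0.12 and -0.88 ± 0.12). MIR31 was higher in both, by 1.03 ± 0.13 and 1.33 ± 0.12.

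Fewer features were seen in HCT116. The HCT116 DMSO library held counts for 727 features and the MCF7 DMSO library for 1588. Thinned to the same 3035608 reads, MCF7 DMSO still held a mean of 1331 over 20 draws, 1.83 times as many. This argues against sequencing depth as the whole cause, although thinning did lower the number.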
